A study of Rattus norvegicus with 6 samples.

How the data were processed

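Total RNA from rat spinal cord at about thoracic segment 8 was measured on 6 one-colour oligonucleotide arrays. According to the labels, 3 arrays came from the epicenter of a contusion injury at day 35 and 3 from the matching position of uninjured animals. A contusion is a blunt blow to the exposed cord, and the epicenter is the tissue at the point of impact. Groups and replicate numbers were taken from the sample titles. The labels do not say outright that each array came from its own animal, so p-values measure the spread between these arrays, which may be in part technical.

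The deposited table holds 1 value per probe set and array, an intensity on a linear scale, read as such from the values themselves: they are strongly skewed, and 21 to 32 values per array lie below 0. How the authors summarised probes into probe sets, subtracted background and scaled the arrays is not given in the sources used here. Per array, the mean of the deposited intensities after trimming 2% at each end ran from 209 to 228, a spread of 8.94%. That is within the 10% set beforehand as the limit for a table that needs no further scaling, so the values were used as deposited. The table held 0 columns of other samples.

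Gene names came from the annotation of the array's probe sets, updated through the gene identifier to current rat symbols of the GRCr8 assembly, which was used for names only. The build behind the array design is not given in the sources used here, so no coordinates are printed. Of 8799 probe sets, 59 were controls and were left out of the fits. Among the other 8740, 7006 carried 1 gene, 308 several and 1426 none. Symbols were updated for 6994 probe sets and kept as annotated for 24. Probe sets with no gene or with several were tested but are not named, and a listed gene for which no singly named probe set was found is not analysed here.

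Values under the pooled 25th percentile, a signal of 61.6, were set to that floor, and all values were then transformed to log2, on which the floor is 5.94. A probe set was tested if at least 3 of the 6 arrays lay above the floor, which left 6705. Log2 changes understate the difference wherever values sit at the floor. Where every array of a group lay at the floor, a fold is given as "at least", the brighter group's mean log2 value against the floor. The depth of an array has no count behind it, and the number of arrays, 3 per group with 4 residual degrees of freedom, limits the precision.

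Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, contused against uninjured, with no covariates. Adjusted p-values are Benjamini-Hochberg values from limma over all probe sets tested, and the threshold was 0.05. An exact permutation test of a single value in 3 against 3 arrays cannot go below 0.1, so none was used. Errors of signals are SDs over 3 arrays, and errors of log2 changes of tested probe sets are standard errors from limma's fit. Those of control probe sets, list means and 3' to 5' ratios come from the spread of the arrays within each group, not from limma. For gene lists, each gene was represented by its tested probe set with the highest mean, which gave 3955 genes. Each list with at least 5 tested genes was tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 42 lists. Camera sets a list's changes against those of all other genes. Camera was also run with the correlation estimated from the arrays, which leaves its test the 4 residual degrees of freedom, and fry was run in its directional form (whether a list's genes move, on balance, one way) and its mixed form (whether they change in either direction). Plots were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

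The 43 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists hold 1302 genes, of which 906 were on the array, 2 of them matched by a synonym. Some genes are on several lists. Named genes are, first, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap and which lie above the floor on all 3 arrays of the higher group and at least 2 of the lower. To these come the 5 brightest genes in each direction with every array of the other group at the floor. For each list, up to 3 risen and 3 fallen members with the smallest p are named, or the 2 with the highest mean where none passed. This gave 133 genes. Of these, 52 had more than 1 tested probe set, and for 16 the probe sets differed in whether they passed the threshold: C1qc, Gch1, Hspb1, Ache, Tac1, Gria2, Grik4, Kcnab2, Fn1, Cspg5, Vcam1, Igfbp2, Alb, Zfp36, Pfkp and Pdha1. None of them had a probe set past the threshold in the opposite direction. Where other genes are named, the text says that they were chosen after their values were seen.

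The procedure was tested on simulated arrays built from the means and spreads of this comparison, with 6651 probe sets tested. It found 70% of changes of 2-fold and 11% of changes of 1.41-fold, 0 in the wrong direction, and 5.81% of what it found was unchanged. Far fewer probe sets were changed in the simulation than were called in the data, which makes the adjusted threshold stricter there. The shares found therefore do not give the share of changes that the fit to the data finds. With no change simulated limma called 0 probe sets, and 341 at an unadjusted p of 0.05. It found 10 of 10 shifted lists and called 0 of 10 unchanged ones, in a simulation whose genes varied independently of each other.

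Alternatives were quantile normalization, scaling to a common median, floors at the pooled 10th and 50th percentiles, no floor, no filter, a filter that needs all 6 arrays above the floor, limma without a trend and with a robust trend, the replicate number as a block, each array left out in turn, stricter thresholds, the mean of a gene's probe sets, and the other set tests. The replicate numbers do not pair the arrays, since the labels tie them to nothing shared.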

Results

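Gene expression was measured in rat spinal cord at about thoracic segment 8, in 3 samples from the epicenter of a contusion injury at day 35 and 3 samples from uninjured cord, each on 1 array. The comparison asks how the chronically injured cord differs from uninjured tissue at the same level. The titles of the uninjured samples give no day and name no sham operation. Effects of surgery, of elapsed time and of processing therefore cannot be told apart from those of the contusion. Median signals ran from 122 to 127 and 73.1% to 76% of probe sets lay above the floor on each array. Across probe sets, log2 signals correlated at 0.958 to 0.977 between arrays of a group and at 0.91 to 0.932 between arrays of different groups. The first principal component, with 60.5% of the variance, separated the 3 contused from the 3 uninjured arrays, and the second held 15.1%. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.08 to 1.12 for the GAPDH control on the contused arrays and 1.13 to 1.17 on the uninjured arrays. For the beta-actin control it was 1.11 to 1.24 and 1.03 to 1.28.

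Of 6705 probe sets tested, 1165 (17.4%) passed an adjusted p of 0.05 in limma, 522 higher and 643 lower after contusion. In 134 the rise, and in 160 the fall, was at least 2-fold. By gene, 277 of 3955 symbols were higher and 392 lower. At an unadjusted p of 0.05, 940 probe sets were higher and 1090 lower. All 3 contused arrays lay on one side of all 3 uninjured arrays for 2333 probe sets (34.8%), against 10% by chance, and the median log2 change over all tested probe sets was -0.005. Leaving out 1 array lowered the count most for contused array 2 (723, with 295 higher and 428 lower) and uninjured array 3 (659, with 276 higher and 383 lower).

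Of the 10 largest rises, 7 were in genes on the microglia and macrophage, lysosome or complement lists. Of the 10 largest falls, 4 were in genes on the cholesterol synthesis list and 3 on the neuron list. Lgals3, the lectin galectin-3 of activated macrophages, rose 8.4-fold, from 259 ± 60.6 to 2139 ± 212 (signal, SD, n = 3; log2 change 3.07, SE 0.18, adjusted p = 1.03e-05). The chemokine gene Cxcl14 rose 6.16-fold, from 353 ± 51.3 to 2162 ± 114, and Arl11, a small GTPase, rose 5.22-fold. Cp, the copper-carrying ferroxidase ceruloplasmin, rose 4.26-fold. C1qb and C1qc, which encode chains of the complement starter C1q, rose 3.85-fold and 3.83-fold. Grn (progranulin, a lysosomal and secreted protein) rose 3.74-fold, the leukocyte tetraspanin Cd53 3.6-fold, the lysosomal protease Ctsd 3.59-fold and Serping1, the inhibitor of C1, 3.45-fold. Scd, which puts the double bond into stearoyl-CoA, fell 6.01-fold, from 545 ± 63.2 to 90.7 ± 11.7 (log2 change -2.59, SE 0.16, adjusted p = 1.18e-05). The neuronal calcium sensor Vsnl1 fell 4.13-fold, from 717 ± 57.5 to 179 ± 60.1. Sqle (squalene epoxidase) and Insig1, an endoplasmic reticulum protein of sterol sensing, fell 4.02-fold and 4.01-fold. Acat2, whose enzyme joins acetyl-CoA units ahead of the mevalonate pathway, fell 3.58-fold, from 616 ± 11.2 to 172 ± 10.1. Pvalb, the calcium-binding parvalbumin of interneurons, fell 3.63-fold and Thy1, a surface glycoprotein of neurons, 3.41-fold. The neuropeptide gene Cck fell 3.4-fold, the neurofilament protein gene Ina 3.39-fold and the sodium channel gene Scn1a 3.38-fold. Without the filter on dim probe sets, Serping1 no longer passed (adjusted p = 0.117).

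**Figure D1:**
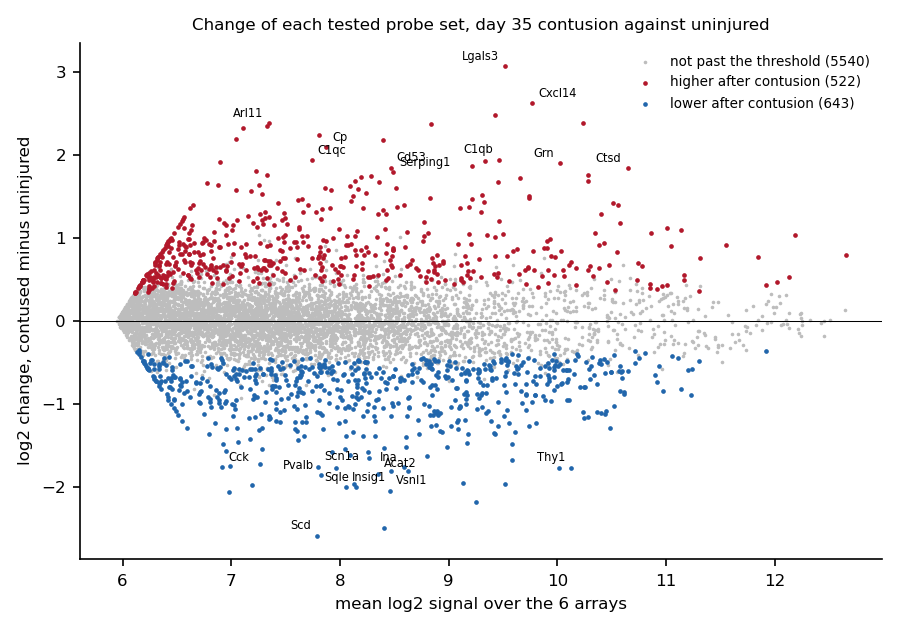
Each point is 1 of the 6705 tested probe sets, with its mean log2 signal over the 6 arrays on the x axis and its log2 change (contused minus uninjured) on the y axis; red points (522) were higher and blue points (643) lower at an adjusted p of 0.05 in limma. The named genes run from Lgals3 at 3.07 to Scd at -2.59, and the slanted edges at the left come from values set to the floor.

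A further 21 genes passed the threshold with all uninjured arrays at the floor, and 13 with all contused arrays there. Brightest among the former were Fcgr2b, an inhibitory receptor for IgG (310 ± 36.4 after contusion, at least 5.01-fold higher), and Hmox1, the heme-degrading oxygenase (232 ± 20.8, at least 3.76-fold higher). Apobec1, a cytidine deaminase that edits RNA, was at least 3.16-fold higher. Gch1, the entry enzyme of tetrahydrobiopterin synthesis, was at least 2.29-fold higher and Soat1, which esterifies cholesterol, at least 2.24-fold. With the floor at the pooled 50th percentile, Gch1 did not pass (adjusted p = 0.285). In the other direction stood Nrgn, the postsynaptic calmodulin-binding protein neurogranin (262 ± 64.4 in uninjured cord, at least 4.17-fold lower after contusion). Lin7b, a synaptic scaffold gene, was at least 2.19-fold lower and the synaptic vesicle gene Svop at least 2.13-fold. Rapgef4, a cAMP-activated exchange factor, was at least 2.01-fold lower and Pdzd4 at least 1.76-fold.

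Of 42 gene lists with at least 5 tested genes, 24 passed an adjusted p of 0.05 with camera at the preset correlation, 16 higher and 8 lower after contusion. With the correlation estimated from the arrays, camera called 0 of 42 (adjusted p = 0.15 or more for each, 13 lists at an unadjusted p of 0.05). Estimates exceeded the preset of 0.01 for most called lists. They were highest at 0.375 for meninges and 0.333 for matrix, and stood at 0.27 for microglia and macrophages, 0.292 for lysosome and 0.219 for neurons. Among called lists they lay below it only for antigen presentation (0.00248), complement (-0.000638), ependyma, cell cycle, and annexins and S100. Where the higher estimates hold, camera's p-values at the preset are too small. Fry's directional test called 23 lists and its mixed test 38. In the following, counts of list members are those past the threshold over all probe sets tested.

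**Figure D2:**
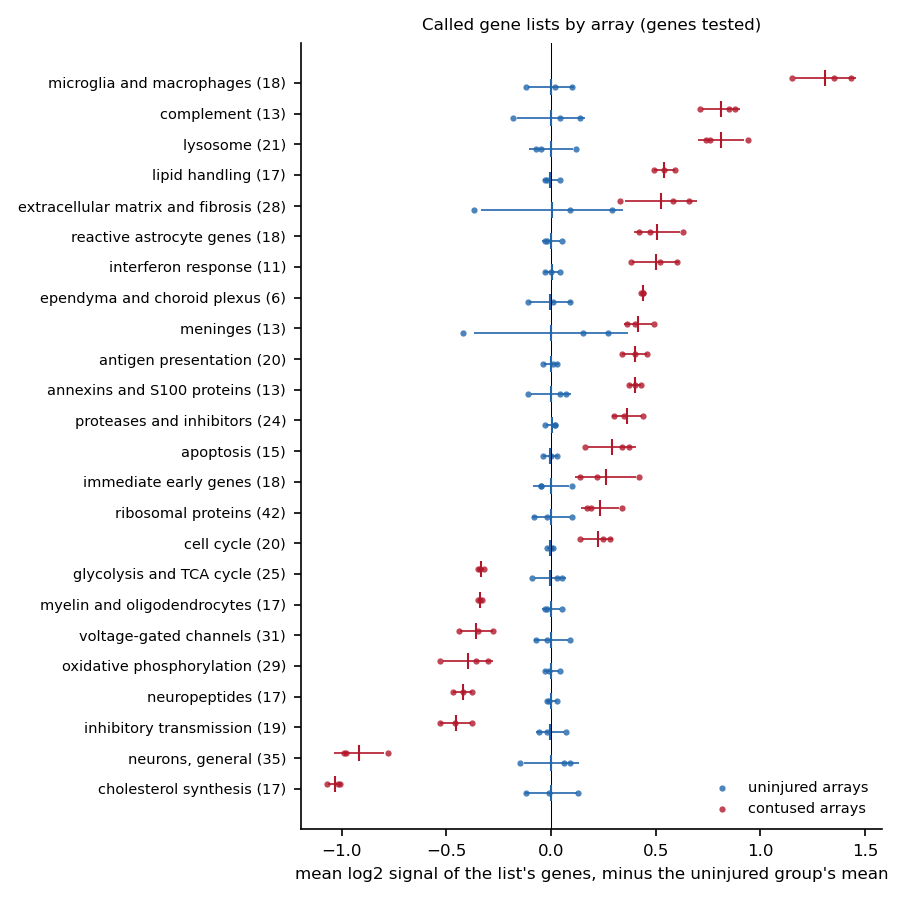
For each of the 24 lists called by camera at the preset correlation, points show the mean log2 signal of the list's tested genes on each of 3 contused (red) and 3 uninjured (blue) arrays, relative to the uninjured group's mean; ticks and bars give each group's mean and SD, and the number of tested genes follows each name. The microglia and macrophage list lay 1.15 to 1.43 above the uninjured mean and the cholesterol list 1.01 to 1.07 below it (-1.01 to -1.07), while the uninjured arrays spread widely for the matrix and meningeal lists.

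Markers of microglia and macrophages rose almost throughout: 17 of 18 tested genes were higher and 0 lower (17 higher when adjusted over the list alone), with a median log2 change of 1.29 (camera adjusted p = 6.48e-16, and 0.15 with an estimated correlation). Lgals3, Fcgr2b and Hmox1 had the smallest p. The exception was Csf1r, the receptor for macrophage colony-stimulating factor, with a log2 change of -0.33; it was singled out after its value was seen. Lysosomal genes rose in 15 of 21 cases with 0 lower (17 adjusted over the list alone), with a median of 0.84 (adjusted p = 1.39e-12, and 0.15 with an estimated correlation). Besides Grn and Ctsd, Cd63, a tetraspanin of late endosomes, rose from 866 ± 56.6 to 2119 ± 217. Complement genes were higher in 7 of 13 cases and lower in 0 (8 adjusted over the list alone; median 0.76, adjusted p = 1.53e-05, and 0.15 with an estimated correlation). They included C1qb, C1qc and Cfd, the protease factor D, at least 1.96-fold higher. Without contused array 2, 4 complement genes were higher.

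Antigen presentation genes were higher in 11 of 20 cases and lower in 0 (11 adjusted over the list alone), with a median log2 change of 0.44 (camera adjusted p = 4.47e-06, and 0.15 with an estimated correlation). B2m, the light chain of class I molecules, rose from 1002 ± 33.3 to 1589 ± 132. The class II genes RT1-DMb and RT1-Da had log2 changes of 0.6 and 0.88. The count was 5, 3 and 9 without contused arrays 1, 2 and 3, and 5, 7 and 3 without uninjured arrays 1, 2 and 3. The call of RT1-Da was lost without contused array 2 (adjusted p = 0.0551) or uninjured array 3 (0.0506). Interferon response genes were higher in 3 of 11 cases and lower in 0 (3 adjusted over the list alone; median 0.35, adjusted p = 0.00109, and 0.15 with an estimated correlation). These were the myeloid transcription factor gene Irf8 (385 ± 12.2 against 150 ± 5.66), the antiviral membrane protein gene Ifitm3 (log2 change 1.43) and the interferon gamma receptor gene Ifngr1 (log2 change 1). Ifngr1 was not past the threshold without contused array 2 (adjusted p = 0.0538) or uninjured array 3 (0.0503).

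No lymphocyte marker passed: 0 of 12 tested T and B cell genes were higher and 0 lower in limma (0 adjusted over the list alone and 0 at an unadjusted p of 0.05), with a median of 0.03 (camera adjusted p = 0.601). The brightest were Il2ra (241 ± 16.1 against 260 ± 31.4 in uninjured cord) and Lck (188 ± 30 against 205 ± 48.9). Of 27 cytokine and chemokine genes, 5 were higher and 1 lower (5 and 2 adjusted over the list alone), and the list was not called (median 0.01, adjusted p = 0.358). Ccl3 rose 1.77-fold, Ccl2, a chemoattractant of monocytes, 1.88-fold and the tumour necrosis factor receptor gene Tnfrsf1a 2.03-fold. Mif fell 1.53-fold, from 1790 ± 154 to 1176 ± 157, a call lost without uninjured array 3 (adjusted p = 0.0586).

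Immediate early genes were higher in 4 of 18 cases with 0 lower (4 adjusted over the list alone; median 0.21, adjusted p = 0.0071, and 0.29 with an estimated correlation). Atf3, a transcription factor of stressed cells, was at least 1.75-fold higher, Zfp36, which destabilises cytokine mRNAs, 1.86-fold and the phosphatase gene Dusp6 2.27-fold. Apoptosis genes were higher in 4 of 15 cases with 0 lower (4 adjusted over the list alone; median 0.18, adjusted p = 0.00803, and 0.29 with an estimated correlation). Among them Gadd45a, induced by DNA damage, rose 2.2-fold, and Casp1, the protease that matures interleukin-1, 1.8-fold. Tnfrsf1a is on this list too. Cell cycle genes had 2 higher and 1 lower of 20 (2 and 1 adjusted over the list alone; median 0.26, adjusted p = 0.0189, and 0.15 with an estimated correlation). The cyclin gene Ccnd2 rose 2.48-fold and the kinase gene Cdk4 1.54-fold, while Stmn1, a regulator of microtubules, fell 1.6-fold. The list's call ended without contused array 2 (adjusted p = 0.0529) and with the floor at the pooled 50th percentile (0.0526). With 1 array left out, Dusp6 (contused array 2, adjusted p = 0.0597), Cdk4 (up to 0.109, without uninjured array 3) and Stmn1 (up to 0.0763, likewise) lost their calls.

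Astrocyte markers as a list were not called: 2 of 18 were higher and 0 lower (2 adjusted over the list alone; median 0.07, adjusted p = 0.355). Fabp7, a fatty acid-binding protein of radial glia and astrocytes, and Gja1, the gap junction protein connexin 43, rose 1.57-fold and 1.58-fold. Their calls were lost with 1 array left out, Fabp7 at an adjusted p of up to 0.0863 (uninjured array 3) and Gja1 at up to 0.144 (uninjured array 3), and the count was 0 without contused array 2 or 3 or uninjured array 3. It was also 0 without the filter on dim probe sets (adjusted p = 0.108 and 0.143). Genes known to rise in reactive astrocytes were higher in 5 of 18 cases and lower in 0 (5 adjusted over the list alone; median 0.28, adjusted p = 0.000676, and 0.15 with an estimated correlation). Led by Cp, they included Hspb1, a small heat shock protein, which rose from 700 ± 79.3 to 2257 ± 396. Timp1, an inhibitor of matrix proteases, rose from 312 ± 21.1 to 650 ± 48.7. None of these 3 genes is made by astrocytes alone.

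Myelin and oligodendrocyte genes were lower in 5 of 17 cases and higher in 0 (5 lower and 1 higher adjusted over the list alone), with a median log2 change of -0.27 (camera adjusted p = 0.00128, and 0.15 with an estimated correlation). Mog, a surface protein of myelin, fell from 859 ± 83.3 to 472 ± 56.7, Enpp2 (autotaxin) from 1158 ± 56.7 to 728 ± 41.8 and Gjb1, the gap junction protein connexin 32, 1.75-fold. Mbp, the myelin basic protein gene, gave 5634 ± 485 against 5622 ± 530 in uninjured cord (adjusted p = 0.986). No tested marker of oligodendrocyte progenitors passed the threshold (0 higher and 0 lower of 9 in limma, 0 adjusted over the list alone and 0 at an unadjusted p of 0.05; median 0.24, adjusted p = 0.263). The brightest of these, the proteoglycan gene Bcan and the transcription factor gene Sox10, had log2 changes of 0.13 and -0.04. Schwann cell markers had 0 of 12 past the threshold in limma, also adjusted over the list alone, and 2 higher at an unadjusted p of 0.05 (median 0, adjusted p = 0.589). Mbp and S100b, with a log2 change of -0.06, were the brightest of them. Mbp is also on the myelin list and S100b on the astrocyte list, so their values do not speak for Schwann cells alone. With quantile normalization 2 Schwann cell genes were higher.

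Of 17 tested genes of the cholesterol synthesis list 13 were lower and 1 higher (14 and 1 adjusted over the list alone), with a median log2 change of -1.06, or 2.08-fold lower (camera adjusted p = 3.72e-10, and 0.15 with an estimated correlation). Scd, Acat2 and Sqle had the smallest p among the falls. The exception, Srebf1, encodes a transcription factor of lipid synthesis genes and rose 2.6-fold, from 231 ± 40 to 597 ± 75.5 (adjusted p = 0.000331). Lipid handling genes moved the other way, with 10 of 17 higher and 1 lower (12 and 1 adjusted over the list alone; median 0.68, adjusted p = 1.53e-05, and 0.15 with an estimated correlation). Plin2, which coats lipid droplets, rose 2.9-fold, from 178 ± 23.7 to 516 ± 36.3. The apolipoprotein gene Apoc1 rose 3.02-fold, from 166 ± 21.1 to 501 ± 69.3, and Soat1 was above the floor on the contused arrays alone. Fabp4, a fatty acid-binding protein of fat cells and macrophages, fell 1.6-fold and was above the floor on 2 of the 3 contused arrays. With no floor it did not pass (adjusted p = 0.0585), and 0 lipid handling genes were lower. Microglia and macrophage markers (median 1.29) rose in the same samples, and neuron and myelin markers fell.

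**Figure D3:**
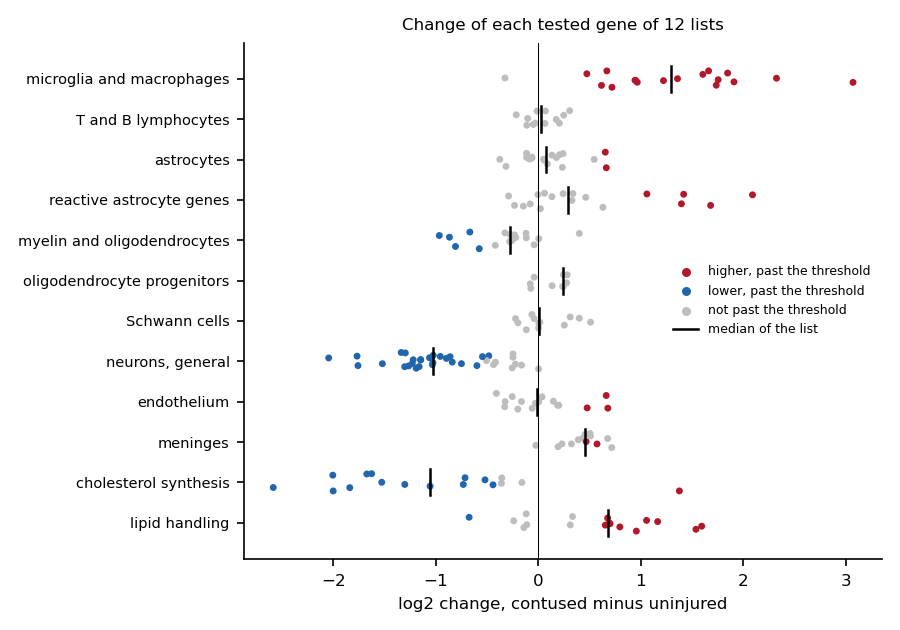
Each point is 1 tested gene of 12 lists, at its log2 change (contused minus uninjured) on the x axis, in red or blue where it was higher or lower at an adjusted p of 0.05 in limma and in grey otherwise; points are spread vertically for legibility and black ticks mark list medians. The medians run from -1.06 for cholesterol synthesis and -1.03 for neurons, over -0.27 for myelin and 0.07 for astrocytes, to 1.29 for microglia and macrophages.

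General neuronal genes fell in 26 of 35 cases and rose in 0 (27 lower adjusted over the list alone), with a median log2 change of -1.03, or 2.04-fold lower (camera adjusted p = 1.43e-17, and 0.15 with an estimated correlation). Thy1 fell from 2076 ± 224 to 607 ± 36.1, Dnm1, a GTPase of synaptic vesicle recycling, from 1327 ± 90.2 to 552 ± 45.8, and Vsnl1 4.13-fold. Motor neuron genes were mixed, with 2 higher and 3 lower of 13 (2 and 4 adjusted over the list alone), and the list was not called (median -0.03, adjusted p = 0.589). Nefh, the heavy neurofilament chain, fell from 2108 ± 121 to 1033 ± 49.5, Ache (acetylcholinesterase) fell 2.15-fold and Slc18a3, the vesicular acetylcholine transporter, 1.49-fold. The homeobox gene Isl2 rose 1.6-fold and the nicotinic receptor subunit gene Chrnb2 1.45-fold. In the sensory ganglia list 1 gene was higher and 1 lower of 9 (1 and 2 adjusted over the list alone; median 0.1, adjusted p = 0.82). These were P2rx3, an ATP-gated channel, at 1.46-fold higher, and the substance P gene Tac1 at 1.62-fold lower. With 1 array left out, Slc18a3 (up to 0.114, uninjured array 3), Chrnb2 (up to 0.154, contused array 1), P2rx3 (up to 0.145, uninjured array 2) and Tac1 (0.0557, contused array 2) went above an adjusted p of 0.05.

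Inhibitory transmission genes were lower in 7 of 19 cases and higher in 0 (8 lower adjusted over the list alone; median -0.25, adjusted p = 0.00128, and 0.15 with an estimated correlation). Gad1, which makes GABA, fell from 432 ± 44 to 165 ± 20.2, Slc12a5, the neuronal potassium-chloride cotransporter, from 863 ± 118 to 306 ± 84.1 and the GABA receptor subunit gene Gabrb2 2.17-fold. Of 27 glutamate transmission genes 3 were lower and 0 higher (3 adjusted over the list alone), and the list was not called (median -0.11, adjusted p = 0.255). The AMPA receptor subunit gene Gria2 fell 2.06-fold, Dlg4, the postsynaptic scaffold PSD-95, 1.62-fold and the kainate receptor subunit gene Grik4 1.47-fold. Grik4 lost its call without contused array 2 (adjusted p = 0.0519) or uninjured array 3 (0.0832). Voltage-gated channel genes were lower in 6 of 31 cases and higher in 0 (7 lower adjusted over the list alone; median -0.18, adjusted p = 0.00578, and 0.22 with an estimated correlation). Kcnab2, an auxiliary potassium channel subunit, fell 2.78-fold, from 959 ± 56.8 to 347 ± 52.1, the calcium channel subunit gene Cacna2d1 2.57-fold and the potassium channel gene Kcnc1 2.61-fold. With all 6 arrays required above the floor the channel list was no longer called (adjusted p = 0.11). Neuropeptide genes were lower in 7 of 17 cases and higher in 0 (7 adjusted over the list alone; median -0.18, adjusted p = 0.00475, and 0.15 with an estimated correlation). Besides Cck, the somatostatin gene Sst fell from 1110 ± 149 to 431 ± 43.3 and the enkephalin gene Penk from 711 ± 26.5 to 330 ± 32. The median of this list was -0.31 without uninjured array 1. General neuronal genes fell in the same samples, with a median of -1.03.

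Matrix and fibrosis genes were higher in 8 of 28 cases and lower in 0 (10 adjusted over the list alone; median 0.48, adjusted p = 7.72e-06, and 0.29 with an estimated correlation). The collagen genes Col15a1 and Col5a2 rose 1.9-fold and 1.58-fold and Fn1 (fibronectin) 2.59-fold, from 395 ± 187 to 939 ± 85.1. Without contused array 2 the count was 2 and without uninjured array 3 it was 4, and in both cases Col5a2 was lost (adjusted p = 0.0635 and 0.0692). Fry's directional test did not call the list (adjusted p = 0.0794). Meningeal markers, which spread in the same way between the uninjured arrays, had 2 of 13 higher and 0 lower (2 adjusted over the list alone; median 0.46, adjusted p = 0.00177, 0.34 with an estimated correlation and 0.111 with fry). Igfbp2, which binds insulin-like growth factors, rose 1.49-fold and Ptgds, a prostaglandin D synthase, 1.38-fold. These calls were lost with 1 array left out, at an adjusted p of up to 0.0774 for Igfbp2 and 0.185 for Ptgds, both without uninjured array 3, and the count was 0 without contused array 2 or uninjured array 3. Without the latter the log2 change of Ptgds went from 0.47 to 0.31 and the median of the list to 0.27 (adjusted p = 0.0499). Proteases and their inhibitors were higher in 9 of 24 cases and lower in 1 (10 and 1 adjusted over the list alone; median 0.31, adjusted p = 0.000538, and 0.15 with an estimated correlation). Without contused array 2 the median was 0.19. A2m, a broad protease inhibitor, rose from 402 ± 51.3 to 1002 ± 146, the urokinase gene Plau 2.23-fold and Timp1 2.08-fold. Mmp10 fell 1.49-fold, a call lost at an adjusted p of up to 0.13 (without uninjured array 3), and Plau did not pass with the floor at the pooled 50th percentile (adjusted p = 0.132). Chondroitin sulfate proteoglycan and axon guidance genes had 1 higher and 1 lower of 19 (1 and 0 adjusted over the list alone; median 0.05, adjusted p = 0.456). Nrp1, a receptor for semaphorins, rose 2.02-fold, and Cspg5 fell 1.37-fold, a call lost with any 1 array left out (adjusted p up to 0.137, without uninjured array 3).

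Endothelial genes were higher in 3 of 16 cases and lower in 0 (3 adjusted over the list alone), and the list was not called, with a median of -0.01, a mean of 0.04 and camera's direction upward (adjusted p = 0.614). The 3 were genes for leukocyte adhesion, Icam1 at 1.6-fold, Vcam1 at 1.58-fold and Selp at 1.39-fold. None of the 3 passed without contused array 2 or without uninjured array 3, and 1 did without uninjured array 1. Without contused array 2 their adjusted p-values were 0.0557, 0.0849 and 0.0677. Smooth muscle and pericyte genes had 0 of 10 past the threshold in limma, also adjusted over the list alone and at an unadjusted p of 0.05 (median 0.22, adjusted p = 0.355), and the brightest, Csrp1 and Tagln, had log2 changes of -0.14 and -0.3. Of 4 tested red blood cell genes, too few for camera, 0 passed in limma, also adjusted over the list alone, and 2 were lower at an unadjusted p of 0.05. The globin genes Hbb and Hbb-b1 had log2 changes of -0.42 and -0.62 (adjusted p = 0.134 and 0.101), and without contused array 3 they passed at -0.61 and -0.93 (0.0237 and 0.00354). Plasma and liver protein genes had 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone; median 0, adjusted p = 0.601), A2m, Alb at 1.43-fold higher and Itih3 at 1.44-fold lower. Alb and Itih3 lost their calls with 1 array left out, at an adjusted p of up to 0.0907 (uninjured array 1) and 0.069 (contused array 2). Ependymal and choroid plexus genes had 2 of 6 higher and 0 lower (2 adjusted over the list alone; median 0.28, adjusted p = 0.0232, and 0.16 with an estimated correlation). They were Vim, the intermediate filament vimentin found in many cell types, which rose from 965 ± 312 to 2464 ± 362, and Sostdc1 at 1.43-fold. Without the filter on dim probe sets this list was not called (adjusted p = 0.0668) and neither gene passed (0.0564 for Vim and 0.0753 for Sostdc1). With 1 array left out, Sostdc1 was lost at an adjusted p of up to 0.162 (without uninjured array 3).

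Skeletal muscle genes, a marker of tissue from outside the cord, had 2 of 18 lower and 0 higher (2 adjusted over the list alone; median -0.08, adjusted p = 0.527). Myh1, a myosin heavy chain, fell from 522 ± 70.9 to 200 ± 40.9 and the troponin gene Tnnc2 was at least 1.66-fold lower. Adipose genes had 1 higher and 1 lower of 8 (1 and 1 adjusted over the list alone; median 0.07, adjusted p = 0.601), namely Cfd and Fabp4, both also on lists above, and with no floor 0 were lower.

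Growth factor and receptor genes had 4 higher and 2 lower of 44 (4 and 2 adjusted over the list alone; median 0.15, adjusted p = 0.0578, and 0.24 with an estimated correlation). The list passed under 9 alternatives, at adjusted p-values of 0.0202 to 0.0495, and its median was 0.09 without contused array 3 and 0.05 without uninjured array 2, where it did not pass. Tgfb1, the transforming growth factor of wound healing, rose 3.11-fold, from 87.6 ± 16.3 to 273 ± 51.2, and its receptor gene Tgfbr1 rose 1.85-fold. Bmp7 was at least 1.7-fold higher. Ntrk2, the receptor for brain-derived neurotrophic factor, fell 2.45-fold, from 252 ± 75.5 to 99.6 ± 8.45, and Fgf9 1.73-fold. Heat shock and folding genes had 2 higher (Hmox1 and Hspb1) and 1 lower of 20 (2 and 1 adjusted over the list alone). Their median was -0.18, their mean 0.01 and camera's direction downward (adjusted p = 0.884). The fall was in Hsph1, a large chaperone, from 529 ± 35.1 to 245 ± 71.1. Without contused array 3 the counts were 3 and 6.

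Annexin and S100 genes, whose products bind calcium, were higher in 4 of 13 cases and lower in 0 (4 adjusted over the list alone; median 0.25, adjusted p = 0.0224, and 0.16 with an estimated correlation). S100a4 rose from 511 ± 48.1 to 1449 ± 212, Anxa1 from 141 ± 51.1 to 405 ± 5.31 and Anxa2 2.07-fold. Uninjured array 3 stood apart for Anxa1 (82.7, against 163 and 178) and Anxa2 (357, against 576 and 621). Both stayed past the threshold with each array left out. This list was not called without the filter on dim probe sets (adjusted p = 0.0993). Iron and heme genes had 2 higher and 2 lower of 11 (2 and 2 adjusted over the list alone; median 0.01, adjusted p = 0.3, 0.51 with an estimated correlation and 0.00461 with fry). Cp and Hmox1 rose, while Hmox2, the constitutive heme oxygenase, fell 1.42-fold and the transferrin receptor gene Tfrc 1.61-fold. These falls were lost with 1 array left out, at an adjusted p of up to 0.132 for Hmox2 and 0.139 for Tfrc, both without contused array 2, and 0 genes were lower without contused array 2 or without any 1 uninjured array. Antioxidant genes had 4 higher and 1 lower of 26 (5 and 5 adjusted over the list alone), a median of -0.06 and a mean of 0.03, with camera's direction upward (adjusted p = 0.859). Ucp2, a mitochondrial carrier, rose 1.72-fold, and the glutathione peroxidase genes Gpx1 and Gpx2 1.91-fold and 1.85-fold, while Gpx4 fell 1.37-fold, a call lost at an adjusted p of up to 0.147 (without uninjured array 3). Without contused array 3 the counts were 3 and 5.

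Oxidative phosphorylation genes fell in 11 of 29 cases and rose in 0 (18 lower adjusted over the list alone; median -0.42, or 1.33-fold lower, adjusted p = 1.45e-06, and 0.16 with an estimated correlation). The complex I and IV genes Ndufa4, Cox5b and Ndufs6 fell 1.63-fold, 1.45-fold and 1.58-fold, Ndufa4 from 1402 ± 8.86 to 864 ± 76.5. Glycolysis and TCA cycle genes fell in 11 of 25 cases and rose in 0 (16 lower and 1 higher adjusted over the list alone; median -0.44, or 1.36-fold lower, adjusted p = 4.04e-05, and 0.16 with an estimated correlation). The phosphofructokinase gene Pfkp fell 1.63-fold, the pyruvate dehydrogenase gene Pdha1 1.54-fold and the malate dehydrogenase gene Mdh1 1.44-fold. With 1 array left out the oxidative phosphorylation count was 7 (contused array 1), 5 (uninjured array 2) and 4 (uninjured array 3). The glycolysis count was 7 and 6 without contused arrays 1 and 2, and 4 and 2 without uninjured arrays 2 and 3, where Mdh1 was lost without the latter (adjusted p = 0.0641). Neuron markers fell in the same samples, with a median of -1.03. Ribosomal protein genes were higher in 6 of 42 cases and lower in 0 (5 adjusted over the list alone; median 0.24, adjusted p = 2.87e-05, 0.34 with an estimated correlation and 0.066 with fry). Rpl22 rose 1.45-fold and Rpl30 1.83-fold, and Rps24 was at least 1.41-fold higher. Without contused array 2 the ribosomal count was 2, and without uninjured arrays 1 and 3 it was 0 and 1. Each of the 3 genes lost its call with uninjured array 1 left out, at adjusted p-values of 0.056, 0.0575 and 0.0709.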

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

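The array carries 10 rat control probe sets that were left out of the fits. For 2 of them, both of the beta-actin control, every contused array lay above every uninjured array. A separation in one direction or the other falls to 10% of probe sets by chance, but held for 34.8% of those tested here. No explanation was tested. The 3' probe set of the beta-actin control had a log2 change of 0.34 (SE 0.08), with signals of 3907 ± 399 after contusion and 3072 ± 61.7 in uninjured cord (SD, n = 3). Its middle probe set had a log2 change of 0.27 (SE 0.14), with 4383 ± 655 against 3625 ± 284. The 5' probe set of the same control stood at 0.31 (SE 0.17), with overlapping groups. In the other direction, every contused array lay below every uninjured array for the 3' probe set of the GAPDH control, at -0.15 (SE 0.06). All 4 kept their sign under quantile normalization (0.31, 0.17, 0.31 and -0.18) and under scaling to a common median.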

How the results depend on the processing

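Of the 1165 changed probe sets, between 51.8% (no filter on dim probe sets) and 99.1% (scaling to a common median) were also called under each alternative fit, and none in the opposite direction. Among fits to all 6 arrays, counts differed most without the filter on dim probe sets (662, with 266 higher and 396 lower). There the 1529 probe sets at the floor on every array, which hold no spread between arrays, enter the fit and its variance trend. Log2 changes were as in the main fit, such as 1.79 for Serping1, 1.37 for Fn1 and 1.4 for Vim. Those genes lost their calls through the p-values alone, not through smaller changes. The cause was not tested. A change of at least 2-fold left 294 (134 higher and 160 lower), and an adjusted p of 0.01 left 582 (236 and 346), by construction. With 1 array left out, the count ran from 659 to 1260, that of higher probe sets from 276 to 484 and that of lower ones from 383 to 776. The replicate numbers do not pair the arrays: deviations of same-numbered arrays from their group means correlated at 0.04, 0.22 and -0.24. A fit with the replicate number as a replicate block gave 1200 changed probe sets (535 higher and 665 lower) and 25 lists. Of the 24 called lists, at least 21 kept call and direction under each alternative except camera with an estimated correlation, which called 0. Its test then had 4 degrees of freedom, and its correlations exceeded the preset for most of the called lists. Fry's mixed test, which asks another question, called 38. List member counts moved by more than 1.5 times and at least 2 genes without the filter for astrocytes (0 higher), ependyma (0), lysosome (9), complement (3), antigen presentation (4), reactive astrocyte genes (3), lipid handling (6), matrix (1), annexins and S100 (1), antioxidant (1), ribosomal (1), inhibitory transmission (4 lower), oxidative phosphorylation (7) and glycolysis (5). They moved likewise with quantile normalization for oxidative phosphorylation (7 lower) and for ribosomal (11 higher) and Schwann cell genes (2). Smaller moves, such as from 2 genes to 1, are not given. With the floor at the pooled 50th percentile they did so for cytokines (3 higher), endothelium (1), immediate early genes (2) and antioxidant genes (3 lower). With all 6 arrays above the floor this held for voltage-gated channels (3 lower), with scaling to a common median for antioxidant genes (3 lower), and with the replicate block for meninges (4 higher) and antioxidant genes (4 lower). Medians of called lists moved by more than 1.5 times for complement (0.47) and neuropeptides (-0.04) without the filter, and for annexins and S100 (0.12) there and with the floor at the pooled 10th percentile (0.11). They did so for neuropeptides with that floor (-0.1) and with no floor (-0.08), for myelin with quantile normalization (-0.16), and with the mean of a gene's probe sets for immediate early (0.36) and apoptosis genes (0.11). Of 123 named genes past the threshold, 92 stayed past it with each array left out, 37 lost it without the filter, and at most 5 of those still tested lost it under any other scaling, floor or variance model. Those 37, at adjusted p-values of 0.0531 to 0.211, were Serping1, RT1-Da, Mif, Ifngr1, Fabp7, Gja1, Chrnb2, Slc18a3, P2rx3, Tac1, Gria2, Col15a1, Fn1, Col5a2, Nrp1, Cspg5, Mmp10, Vcam1, Ptgds, Vim, Sostdc1, Alb, Itih3, Tnnc2, Ntrk2, Dusp6, Hsph1, Cdk4, Stmn1, Anxa1, Anxa2, Tfrc, Gpx1, Gpx2, Gpx4, Rpl30 and Rps24. Directions turned only in lists and genes that passed in neither setting, and the cause was not tested. Under quantile normalization the heat shock list turned upward in camera's direction at a median of -0.09, Sox10 changed by 0.07 and Mbp by -0.08. The heat shock list also turned with the floor at the pooled 10th percentile (-0.13) and with fry (-0.18), the antioxidant list without the filter (-0.06), and the sensory ganglia list with all 6 arrays above the floor (-0.11) and with fry (0.1). With 1 array left out, medians ran from -0.24 to -0.05 for the heat shock list, from -0.14 to 0.01 for antioxidant genes and from -0.08 to 0.13 for adipose genes. They ran from 0.12 to 0.2 for oligodendrocyte progenitors (0.24 with all arrays) and from 0.12 to 0.25 for smooth muscle and pericytes (0.22). For glutamate transmission they ran from -0.18 to -0.04 (-0.11). Single genes ran from -0.23 to 0.07 for Lck, from -0.11 to 0.01 for Sox10, from -0.07 to 0.07 for Mbp and from -0.14 to 0.06 for S100b. Low signal limits what can be seen: a fold against a group at the floor is a lower bound, and with the floor at the pooled 50th percentile the log2 change was 0.89 for Hmox1 (1.91 before), -1.04 for Nrgn (-2.06) and -0.83 for Cck (-1.77).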

Other observations

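Some other gene families held many genes below 0 after contusion; they were picked because falls among their genes had been seen, so no p-value is given for them as families. Of 27 tested genes whose symbols begin with Nduf, most of them subunits of respiratory complex I, 17 passed the threshold in limma, all lower, and all 27 had a log2 change below 0 (median -0.6). Of the 27, 6 are on the oxidative phosphorylation list. Ndufa8 fell from 988 ± 93.6 to 504 ± 53.9 and Ndufb8 from 1564 ± 72.9 to 915 ± 203 (SD, n = 3). Subunits of the V-ATPase, the proton pump of lysosomes and synaptic vesicles, were lower in 4 of 8 cases and higher in 0 (median -0.52), whereas 15 of 21 genes of the lysosome list were higher. Atp6v1a fell from 814 ± 85.4 to 430 ± 194, and Atp6ap1, on both lists, had 1099 ± 149 against 1090 ± 41.5. Among 14-3-3 proteins 3 of 6 were lower (median -0.37), led by Ywhag, from 1611 ± 72.3 to 928 ± 124. Proteasome subunit genes were lower in 3 of 24 cases and higher in 0 (median -0.22), and 21 of the 24 lay below 0. Psmb8 and Psmb9 were above 0, with log2 changes of 0.384 and 0.362 that did not pass the threshold. These medians stayed below 0 under both scaling alternatives.

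Genes for calcium-binding proteins of neurons, also picked because falls among them had been seen, were lower in 8 of 11 cases and higher in 0. Pcp4 fell from 636 ± 10.7 to 240 ± 12.1, Calb2 (calretinin) from 481 ± 47.7 to 183 ± 11.6, and Cabp1 from 443 ± 43.7 to 175 ± 3.34. Calm2 and Hpcal4 did not pass in limma (adjusted p = 0.101 and 0.152), and Ncs1 had a log2 change of 0.102 (0.758). Probe sets of Igf1, the gene for insulin-like growth factor 1, differed: 1 of 4 had a log2 change of 1.45 (SE 0.25, adjusted p = 0.00267), and the brightest, which stood for the gene in its list, 0.09 (SE 0.13, adjusted p = 0.711).

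In what follows, the tests of the 3 patterns were chosen after the results were seen, and the counts over other splits were planned. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Only 1 of the 10, the real one, gave as many as 1165 probe sets in limma. Each of the others mixes both groups and gave 0, with at most 319 at an unadjusted p of 0.05. For gene lists it was again 1 of 10, with 24 in the real split and at most 14 in another. Camera at the preset correlation called 4 to 14 lists in those other splits. Each of them holds unequal shares of the groups on its 2 sides, so part of the real difference remains. That difference also widens the spread within each side, which lowers limma's counts. Neither the 0 probe sets nor the 4 to 14 lists therefore measure how often a call is false.

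Neuronal genes were lower by a median log2 of -1.03. If entering cells had only diluted the resident tissue, with its expression unchanged, the neuron, myelin and astrocyte lists would fall alike. The neuron list mean changed by -0.8 (SE 0.09) relative to the mean of the other 2, with no overlap between the groups. This argues against such an even dilution as the whole cause. Reactive astrocyte genes were higher in the same samples (median 0.28), so induced genes may offset a dilution of the astrocyte list. List means changed by -0.91 for neurons, -0.34 for myelin and 0.11 for astrocytes. The 3' to 5' ratios of the GAPDH and beta-actin controls differed by -0.01 on the log2 scale (SE 0.06), within their error, and with 2 control genes a part played by degraded RNA cannot be told apart. A loss of neurons, lower expression in surviving ones, and a different share of grey matter in the samples stay open, as hypotheses that were not tested.

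Cholesterol synthesis genes were lower by a median of -1.06. The cholesterol list changed by -0.69 (SE 0.06) relative to the myelin list mean. This argues against loss of oligodendrocytes, which make much of the cord's cholesterol, as the whole cause only if that mean tracks these cells. The myelin list's genes differed, with log2 changes of -0.87 for Mog, -0.81 for Gjb1 and 0.004 for Mbp. Whether their mean tracks oligodendrocytes was not tested. Relative to the neuron list mean the cholesterol list changed by -0.12 (SE 0.1). A loss of neurons as the whole cause thus cannot be told apart, because both lists moved by about the same amount. Lower activity of the sterol regulatory transcription factors cannot be told apart either: 8 other genes that they control, on none of the fixed lists, had a median of -0.66, but 6 of the 8 had been seen to fall before they were listed, which leaves too few for a test. Among the 8, Acaca had a log2 change of 0.415 (adjusted p = 0.0692), and Srebf1, a gene for one of these factors, rose.

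Matrix genes were higher by a mean log2 of 0.52 (SE 0.21, 27 genes) and meningeal genes by 0.4 (SE 0.19, 12 genes), with no gene counted in both. More meningeal tissue in the contused samples, as the whole cause, would raise both alike. The matrix list changed by 0.12 (SE 0.08) relative to the meningeal list, so more meningeal tissue as the whole cause cannot be told apart, since the difference lies within 2 SE. Uninjured array 3 stood apart from the other uninjured arrays in both, at -0.35 for matrix and -0.38 for meningeal genes, against 0.08 and 0.28, and 0.14 and 0.24. The amount of membrane left on the dissected cord may therefore differ between samples, and newly laid scar matrix stays open as an untested hypothesis.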
